A study of Rattus norvegicus with 6 samples.

How the data were processed

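Cells were dissociated from large (over 300 µm) and small (under 150 µm) mesenteric arteries of adult male Sprague-Dawley rats. Per the labels' protocols, the arteries were digested for 40 min at 37 °C with collagenase II (427 U/mL), papain (13 U/mL) and DNase (150 U/mL) beside dithiothreitol (1 mg/mL), passed through a 70 µm strainer and spun at 1050 rpm for 10 min. Libraries were 10x Genomics 3′ libraries, with 3 samples of each size. Per the submitters' processing notes, reads were converted with bcl2fastq 2.20.0.422 and processed with Cell Ranger on the rat genome build 6.0. Those notes name Cell Ranger 3.1.1 and 3.2.2, while the headers of the count matrices name 3.1.0. The annotation release, the authors' filter on cells, any removal of doublets and the way cell types were assigned are not given in the sources used here.

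The deposited matrices hold raw UMI counts per gene and barcode, per the file headers, for 25199 genes and 58695 barcodes. The cell metadata deposited by the authors list 45921 cells with their total counts, detected genes, percent of mitochondrial UMIs, sample, cell type, subtype and a further cell type label. Its totals differed from the matrix sums by at most 114 UMIs. The kept cells had 310 to 2472 detected genes and at most 7.67 percent mitochondrial UMIs, and 7372 of the 12774 barcodes left out by the authors lay inside those ranges. A further deposited table, named as counts, holds natural log values: its values for the 1103 cells of large 07 are the natural log of 1 plus 10000 times the count over the cell's total, which gave back 99.9 percent of the nonzero counts within 0.01. The other 44818 columns of that table were not used here. All tests used the raw counts. Gene symbols came from the files; 277 genes share a symbol with another gene and were kept as separate genes.

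The authors' cells and cell types were used as given. Their mesenchymal class is called fibroblasts here, from its high fibroblast markers, and their vascular smooth muscle class smooth muscle. Raw counts were summed per sample and cell type, and sums of at least 10 cells entered the tests. Total UMIs of the kept cells were 6944218, 3352225 and 16690370 in large 06, 07 and 08 and 42747358, 5158111 and 24585759 in small 06, 07 and 08. The endothelial sums rested on 261, 82 and 785 cells in the large and 1539, 79 and 855 cells in the small samples, and the fibroblast sums on 604 to 16351 cells. Smooth muscle had 1, 0 and 1191 cells in the large samples, so the planned test could not be fitted with replicates in both groups. It was replaced by the description given with the results: genes with a mean of at least 20 CPM in which large 08 lay at least 2-fold beyond each small sample, with exact Poisson intervals at 95% and list medians set against 10000 random lists.

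Sums were compared, small minus large, with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3. The SE of a log2 change was taken as its size over the square root of the F statistic and is approximate. Cell type shares were compared by two-sided exact permutation tests. The difference of the effect between cell types was tested as an interaction in edgeR. Gene lists were tested with camera from limma 3.58.1 with the inter-gene correlation preset at 0.01, where at least 4 members passed the filter. There were 24 gene lists and 18 marker lists, and of their 668 genes 630 were found by symbol, 10 by synonym and 28 not at all. Several lists share members, such as Gja5, Fabp4 and Sparc. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5 and matplotlib 3.10.9 did the rest.

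The comparisons, the lists, the markers, the rule for named genes and the alternatives listed below, other than those said to be chosen later, were set before the data were examined. Named genes were the 12 of largest log2 change in each direction among genes with adjusted p under 0.05, a mean of at least 20 CPM, groups that do not overlap and a symbol that is not a placeholder (5 in each direction for other cell types). Where fewer than 5 passed in a direction, the 5 of lowest p were named, and up to 4 members of lowest p were named per list. The same rule without the demand on groups named 10 genes of the interaction. A few genes that the rule names are withheld for evaluations and are not printed or drawn. Subtypes were tested after the data had been seen. Genes named there were those that passed the same conditions. Genes named for fibroblast subtype 2, for levels per cell type or as examples of a list were chosen after their values were seen.

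Alternatives were DESeq2 1.42.0, size factors, no filter on genes, stricter filters on cells (at least 1000 UMIs and 500 genes, or at most 5% mitochondrial UMIs), the sample number as a block and leaving out each sample. Lists were also tested with an estimated correlation and with fry. Scrublet, at an expected rate of 0.06, called 73 cells (0.159%), far below that rate. Whether it failed or doublets had already been removed is not known. The cells with the top 5% of scores were therefore removed as a further alternative. That removal, the further cell type label and fits on samples 07 and 08 or 06 and 08 alone were chosen after seeing the data. Equal numbers (06, 07, 08) are not explained in the labels. The deviations of same-numbered samples from their group means correlated by 0.214, 0.136 and 0.223 in endothelial sums, 0.567, 0.370 and 0.447 in fibroblast sums and 0.370, 0.271 and 0.621 in the neuron class. In these 3 types the numbers may pair the samples. In immune cells (-0.0105, 0.0230 and 0.269) and in the subtypes, such as fibroblast subtype 1 (0.108, 0.212 and 0.0502), at least 1 pair did not pass 0.1. All are sums of the same libraries, so the pairing stays unsettled. The main tests stayed without a block, as planned, and fits with the block are given as alternatives.

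The edgeR tests of endothelial, fibroblast, immune and neuron sums, and of the interaction of endothelium with fibroblasts, were run on simulated counts. These had 200 changed genes and were drawn from the real means and library sizes, and camera was run on a list of 20 genes shifted 1.5-fold. The subtype fits, the smooth muscle comparisons and the permutation tests were not simulated. At a 4-fold change edgeR recovered 92.4% of changed genes in endothelial sums (7892 genes), 93.9% in fibroblast sums (10438 genes), 48.5% in immune sums (8211 genes) and 42.4% in the neuron class (1122 genes). At 2-fold the shares were 26.9%, 13.4%, 4.48% and 0, and at 1.5-fold none was recovered. False calls made up 16.0%, 6.58%, 12.5% and 3.45% of calls. The interaction recovered 95% of 4-fold changes among 9766 genes, and false calls made up 7.32% of its calls. Recovery was not measured apart for genes near 0 in 1 of the cell types, so the 95% may not hold for them. Changes of 1.5-fold in single genes were therefore not detectable at this depth and number of samples.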

Results

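Single-cell RNA profiles were collected from the mesenteric artery tree of adult male Sprague-Dawley rats, from large arteries wider than 300 µm, which conduct blood to the gut, and from small arteries under 150 µm, which set resistance to flow. Each size gave 3 samples, numbered 06, 07 and 08. The question was how the cell types of the artery wall differ between conduit and resistance vessels. The labels give 6 rats with 3 rats per sample and 3 samples per group. Read as stated, 3 separate samples of 3 rats would need more than 6 rats, so samples within a group share animals. Which samples share rats is not given. The p-values of genes and shares below measure the spread between samples, which are not independent animals. The camera p-values of lists compare a list's genes with the other genes at a preset correlation. They do not measure the spread between samples alone. The cells kept by the authors numbered 3330, 1103 and 6403 in the large samples and 22941, 1414 and 10730 in the small samples. Their summed UMIs ran from 3352225 in large 07 to 42747358 in small 06, and the median UMIs per cell from 1489 in small 06 to 3609 in small 07. Values of a gene are CPM, scaled UMI counts of a cell type's sum in a sample, as mean ± SD of 3 samples per group. For single genes compared between artery sizes, the scaling used library sizes adjusted by TMM within each comparison. Summed markers, levels averaged over both artery sizes and the CPM quoted for 3 counts were scaled to the raw total of the sum. Values of the same gene can therefore differ slightly between passages. Log2 fold changes are small minus large, ± SE.

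Fibroblasts were the most common cells of the small arteries and immune cells were common in 2 of the large samples. Fibroblasts made up 31.1%, 54.8% and 55.1% of the cells in the large samples and 71.3%, 82.4% and 71.7% in the small samples (47.0% ± 13.7 and 75.1% ± 6.31, SD, n = 3). Immune cells made up 60.2%, 34.9% and 12.6% in the large samples against 13.7%, 7.43% and 9.68% in the small samples. Endothelial cells, which line the vessel, took 9.18% ± 2.68 in large and 6.75% ± 1.19 in small arteries. Smooth muscle cells, the contractile layer, made up 18.6% of large 08 but 1 cell of large 06 and 0 of 1103 cells of large 07 (which allows a share of up to 0.272%), against 6.68%, 0.849% and 8.09% in the small samples. A mixed class labelled neuron by the authors took 1.70% ± 1.07 and 2.68% ± 1.03. In two-sided exact permutation tests, which cannot go below p = 0.1 with 3 samples against 3, the fibroblast share gave p = 0.1, the immune share p = 0.2, the endothelial and neuron shares p = 0.3 and the smooth muscle share p = 1. Adjusted over the 5 shares the first 4 came to 0.375, so no share passed. Between samples of equal number, the fibroblast and neuron shares were higher and the immune and endothelial shares lower in the small sample in all 3 pairs (exact sign-flip p = 0.25 each, the smallest possible with 3 pairs), and the smooth muscle share was higher in 2 pairs and lower in 1. The fibroblast difference was 28.1 percentage points over all cells and 8.88 points when smooth muscle, endothelial cells and fibroblasts alone were counted.

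**Figure D1:**
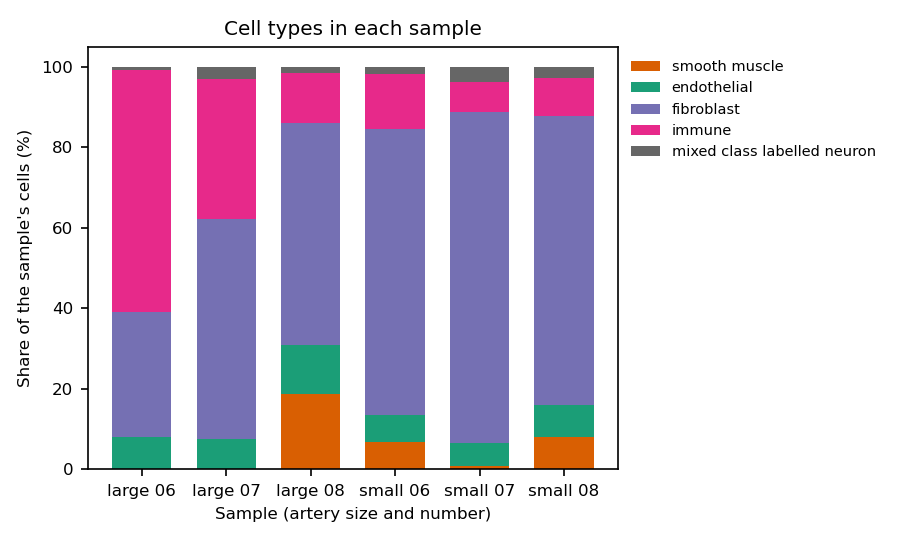
Share of each sample's cells in percent (vertical axis, stacked bars) by cell type in the 3 large and the 3 small samples. Fibroblasts reach 71.3% to 82.4% in the small samples, and smooth muscle cells are nearly missing from large 06, large 07 and small 07.

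The endothelium held a pair of subtypes whose proportions shifted with artery size. Subtype 1 carried the genes of blood vessel endothelium: Gja5, the connexin of arterial gap junctions, stood at 945 ± 385 CPM (SD, n = 6) against 3.24 in subtype 2, and Nos3, the endothelial nitric oxide synthase, at 347 ± 70.6 against 47.7 ± 93.8. Subtype 2 carried the genes of lymphatic vessels: the summed lymphatic markers, which include Prox1, Lyve1, Ccl21, Flt4 and Reln, averaged 95635 CPM there and 164 CPM in subtype 1. Subtype 2 also held more Piezo2, a mechanically gated channel (51.7 ± 17.3 against 0.233 CPM), more Gja1 (442 ± 143 against 93.9 CPM) and more Ednrb, the endothelin B receptor (153 ± 48.3 against 8.06 CPM). Subtype 1 made up 84.7%, 61.0% and 81.3% of endothelial cells in the large samples and 38.1%, 21.5% and 26.0% in the small samples. The shares did not overlap (75.6% ± 12.8 against 28.5% ± 8.61, SD, n = 3; two-sided exact permutation p = 0.1, the smallest possible; 0.4 adjusted over 8 subtype shares). Chance alone keeps the groups apart in 10% of such comparisons. The lymphatic marker sum over all endothelial cells was 19360 ± 13217 CPM in large and 73107 ± 11187 CPM in small arteries (n = 3; exact permutation p = 0.1).

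Over all endothelial cells, Prox1, F3 and Kdr were among the genes higher in small arteries, and Nos3, Gja5 and Vwf among those higher in large ones. Prox1, the transcription factor that sets lymphatic identity, rose by 2.50 ± 0.33 (adjusted p = 0.00243) from 49.7 ± 8.48 to 280 ± 128 CPM. Grap, an adaptor protein of receptor signalling, rose by 4.10 ± 0.45 (adjusted p = 0.00127), from 4.10 ± 3.94 to 41.8 ± 6.83 CPM. F3, the tissue factor that starts coagulation, rose by 2.90 ± 0.31 (adjusted p = 0.00110), from 9.14 ± 5.59 to 89.1 ± 7.69 CPM. Kdr, the main receptor for vascular endothelial growth factor, rose by 2.02 ± 0.31 (adjusted p = 0.00359), from 146 ± 49.0 to 579 ± 167 CPM. Meox2, a homeobox factor, and Angptl4, an inhibitor of lipoprotein lipase, rose by 2.79 ± 0.32 and 2.03 ± 0.25 (adjusted p = 0.00134 and 0.00166). Gmfg, Pard6g, Fam229a, Ccdc141 and Adgrg3 also rose. In the other direction Nos3 had a log2 change of -1.41 ± 0.25 (adjusted p = 0.00592), from 287 ± 57.7 CPM in large to 105 ± 28.5 CPM in small arteries. Gja5 changed by -1.75 ± 0.31 (adjusted p = 0.00648; 818 ± 173 to 236 ± 97.9 CPM), and Hey2, a Notch target of arteries, by -1.53 ± 0.26 (adjusted p = 0.00526). Vwf, the platelet-binding factor stored in endothelial granules, changed by -1.35 ± 0.26 (adjusted p = 0.0103; 1306 ± 141 to 510 ± 124 CPM).

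Frzb, Aldh1a1 and Slc6a4 were among the named genes, of at least 20 CPM on average, that fell most toward small arteries. Frzb, a secreted Wnt antagonist, changed by -4.97 ± 0.58 (adjusted p = 0.00134; 179 ± 120 to 6.36 ± 2.44 CPM), and Dkk3 by -2.39 ± 0.43. Aldh1a1, which makes retinoic acid, changed by -4.14 ± 0.65 (adjusted p = 0.00375; 57.7 ± 41.4 to 2.66 ± 2.74 CPM). Slc6a4, the serotonin transporter, changed by -3.31 ± 0.29 (adjusted p = 6.63e-04; 148 to 13.7 CPM). Pde3a, a phosphodiesterase inhibited by cyclic GMP, changed by -2.75 ± 0.29 (adjusted p = 0.00110; 62.1 ± 5.10 to 8.72 ± 2.93 CPM). Ackr4, a scavenging chemokine receptor, and Fn1, fibronectin, changed by -2.63 ± 0.30 and -2.02 ± 0.37. Cd82, Gask1b, Meis1 and Scx were lower as well.

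In all, edgeR called 645 of 7892 genes in endothelial sums at an adjusted p under 0.05, 327 higher in small and 318 higher in large arteries. DESeq2 called 459. With the sample number as a block 1144 genes were called, 642 of them shared. Without large 08 the count was 263, without small 06 it was 383 and without small 08 it was 222. Of the 78 named genes called here, 41 kept their call without each of the 6 samples in turn, and these include the genes given above from Prox1 to Scx. The other named genes lost it without at least 1 sample. Angpt2, an angiopoietin (15.6 ± 16.5 to 79.0 ± 29.6 CPM; 2.90 ± 0.52), had adjusted p = 0.00636 with all samples and 0.078 without large 08. Ptx3, Nrcam and Mthfd2 completed the 24 named genes of largest change and each lost its call without 2 of the samples: Ptx3 without large 06 or large 08, Nrcam without large 08 or small 08, and Mthfd2 without large 06 or small 08. Fibroblast markers were also higher in the endothelial sums of small arteries, at 2078 ± 290 against 874 ± 271 CPM (n = 3; exact permutation p = 0.1), and pericyte markers lower, at 75.1 ± 4.82 against 267 ± 147 CPM (p = 0.1).

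Much of this difference was smaller within a subtype. Of the 645 genes, 403 could be tested in subtype 1, where the median ratio of the log2 change to that in all endothelial cells was 0.420, and 302 in subtype 2, where it was 0.192. In the first, 94.0% kept their direction and 19 were called, and in the second 75.8% and 7. The shares of the subtypes alone gave a median of 0.640 of the observed change. Within subtype 1, Nos3 changed by -0.22 ± 0.24 (edgeR adjusted p = 0.973; 377 ± 7.98 against 338 ± 59.7 CPM), Gja5 by -0.57 ± 0.32 (0.861), Hey2 by -0.27 ± 0.37 (0.982) and Vwf by -0.07 ± 0.27, and none of these passed. Within subtype 2, Prox1 changed by 0.59 ± 0.27 (0.544), Kdr by 0.38 ± 0.25 (0.671) and Angptl4 by 0.23 (0.808), and none of these passed.

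Within subtype 1, the blood vessel endothelium, Slc6a4, Frzb and Pde3a were higher in large arteries, and F3 and Igf2, an insulin-like growth factor, were higher in small ones. Slc6a4 fell from 205 ± 12.7 to 45.7 ± 18.5 CPM (-2.23 ± 0.34; adjusted p = 0.0222), Frzb from 260 ± 210 to 8.63 ± 9.61 CPM (-4.43 ± 0.69; 0.0222) and Pde3a from 86.0 ± 7.44 to 30.8 ± 13.2 CPM (-1.70 ± 0.30; 0.0299). Lsamp, a cell adhesion protein, stood at 51.8 ± 20.7 CPM in large samples and at 0 in all small samples (adjusted p = 0.0111); 3 counts over the small samples would be 1.55 CPM, but 75.6 CPM in small 07 alone. F3 rose from 9.12 ± 1.65 to 87.1 ± 41.9 CPM (2.78 ± 0.37; 0.0111) and Igf2 from 254 ± 14.6 to 695 ± 145 CPM (1.43 ± 0.26; 0.0299). Fabp4, a fatty acid carrier of capillaries and adipocytes, was called higher in small arteries (4.33 ± 0.83; 0.0364), although its groups overlapped. So did those of Ccl21, a lymphatic marker (19.5 ± 12.6 to 90.5 ± 72.7 CPM; 0.0364), Hbb-bs, a hemoglobin chain of red blood cells (32.6 ± 40.9 to 854 ± 940 CPM; 0.0299), and Ccl5, a chemokine of T cells (7.72 ± 12.2 to 40.9 ± 35.8 CPM; 0.0222), all called higher in small arteries and picked out after their values were seen. Others were Igfbp6, Gpx3, Chit1, Dcn, Rgs10, C1s and Sparcl1, higher in small arteries, and Clic2, Mtss1, Colec12 and Meis1, higher in large ones.

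edgeR called 25 genes in subtype 1, 13 higher in small arteries and 12 higher in large ones, with 383 at an unadjusted p under 0.05, and DESeq2 called 11. Each of the 20 named genes lost its call without at least 1 sample, with F3 at adjusted p = 0.065 without small 08, Slc6a4 at 0.078 and Frzb at 0.055 without small 06, and Lsamp at 0.07 without large 08. The count was 145 without large 06, 11 without large 07, 16 without large 08, 9 without small 06 and 3 without small 08. The sum of small 07 rested on 17 cells and 39696 UMIs. Fibroblast markers in subtype 1 stood at 895 ± 218 CPM in large and 1892 ± 437 CPM in small arteries (exact permutation p = 0.1). Several of the genes that rose, namely Dcn, F3, Gpx3, Igfbp6, C1s and Sparcl1, were abundant in fibroblasts, whereas Igf2 averaged 7.69 CPM there. Erythroid markers in subtype 1 were 23.2, 399 and 13.1 CPM in the large and 2118, 101 and 5345 CPM in the small samples (exact permutation p = 0.2).

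Within subtype 2, the lymphatic endothelium, Ackr4, Thbd and Ptgs1 were among the genes higher in large arteries. Ackr4 fell from 143 ± 59.0 to 7.34 ± 4.08 CPM (-4.28 ± 0.46; edgeR adjusted p = 5.88e-04). Thbd, thrombomodulin, fell from 751 ± 318 to 216 ± 29.0 CPM (-1.75 ± 0.29; 0.0354), and Ptgs1, cyclooxygenase 1, changed by -2.14 ± 0.36 (0.0354). Procr, the protein C receptor that works with thrombomodulin, Bmp4, Bcam, Efemp1 and Cpe were lower too, and Fabp4 rose by 3.45 ± 0.67. All of these lay just under the threshold, with edgeR adjusted p = 0.0498 for Bcam and 0.04997 for each of the others. These 9 were all the calls among 284 genes at an unadjusted p under 0.05, and DESeq2 called 14. Without large 06 the count was 0 and Ackr4 had adjusted p = 0.092. It was 1 without large 07, 26 without large 08 and 2 without small 07. The large sums of subtype 2 rested on 40, 32 and 147 cells. Bmp4 was more abundant in subtype 1, at 532 ± 123 CPM in large and 339 ± 80.6 CPM in small arteries. Ackr4 stood at 128 ± 64.0 CPM there in large arteries, close to its level in subtype 2. Whether RNA or cells of subtype 1 contributed to these falls was not tested.

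**Figure D2:**
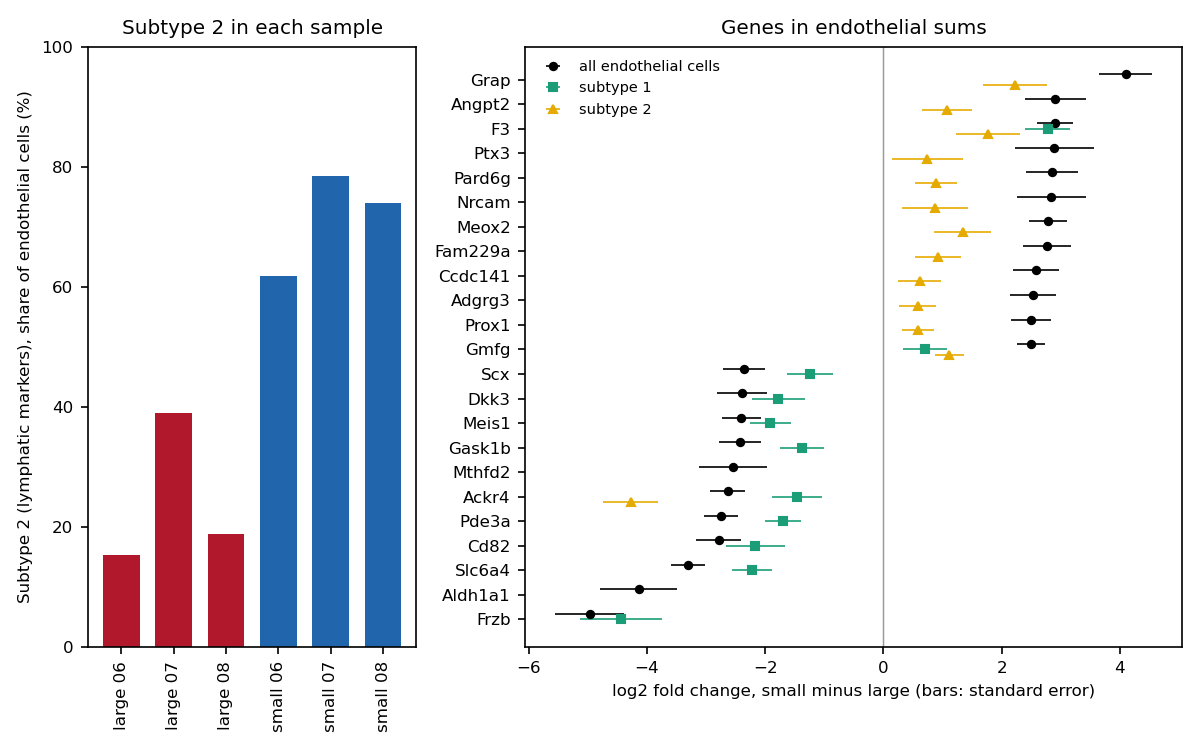
Left, share of subtype 2 among the endothelial cells of each sample in percent; right, log2 fold change (small minus large) ± SE of 23 named genes in all endothelial cells, in subtype 1 and in subtype 2, where tested. The change of Prox1 over all endothelial cells (2.50) shrinks within subtype 2 (0.59), while that of F3 is 2.90 over all endothelial cells and 2.78 within subtype 1.

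Among the fixed gene lists, capillary and fatty acid genes were called higher and antigen presentation genes lower over all endothelial cells of small arteries, each with adjusted p = 0.347 with an estimated correlation. Of 10 capillary members tested, 6 rose, among them Meox2, Kdr, Ca4 and Lpl, and Sparc fell (camera adjusted p = 1.26e-05, median log2 change 1.64). Within subtype 2, which has the lymphatic markers, Kdr changed by 0.38 (edgeR adjusted p = 0.671), Meox2 by 1.34 (0.399) and Lpl by -0.16 (0.901). None of these passed there, whereas Fabp4 was called in both subtypes, with RNA from outside these cells untested. The call over all endothelial cells may therefore follow the shares of the subtypes in part. Fatty acid genes were called up, with 4 of 12 members higher (Angptl4, Fabp4, Lpl and Pparg; adjusted p = 0.0401), and antigen presentation genes down, with 1 of 8 members lower (RT1-A1, -1.11 ± 0.29; 0.0401). Adjusted over the list alone the counts were 8 up and 1 down for capillary genes, 4 up and 1 down for fatty acid genes, and 5 down for antigen presentation genes. Capillary genes stayed called without each sample. Fatty acid genes did not without large 08 (0.228), small 06 (0.0783) or small 08 (0.0754), and antigen presentation genes did not without large 06 (0.232), large 07 (0.292), small 06 (0.0783), small 07 (0.555) or small 08 (0.0754). The basement membrane list had adjusted p = 0.104, and 0.0306 with the sample number as a block.

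Over all endothelial cells single vasoactive genes changed, but camera called none of their lists (0.233 for nitric oxide, prostanoid and endothelin genes), while fry called the nitric oxide, prostanoid and endothelin list down (adjusted p = 0.0258). Of 13 tested genes for nitric oxide, prostanoid and endothelin synthesis, 4 fell and 0 rose (Nos3, Ddah1, Ptgs1 and Ace), with 2 up and 4 down adjusted over the list alone. Of 15 arterial and Notch genes, Dll4, a Notch ligand, rose (1.77 ± 0.28; 29.0 ± 3.12 to 102 ± 30.5 CPM), and Gja5 and Hey2 fell (3 up and 6 down adjusted over the list alone). Of 8 ion channels, Piezo2 rose (2.32 ± 0.35) and Kcnn4, a calcium-activated potassium channel, fell (-1.97 ± 0.36; adjusted p = 0.058 without large 08), the same counts as adjusted over the list alone. Of 25 growth factor genes, 9 rose and 4 fell (12 and 5 adjusted over the list alone), with Tgfbr2 higher and Bmp4 and Ccn1 lower. Of 14 collagen and proteoglycan genes, 3 rose and 4 fell, among them Dcn up and Fn1 and Bgn down (9 and 4 adjusted over the list alone). Of 11 venous genes, 2 rose and 3 fell in both counts, among them Lrg1 up and Vwf, Vcam1 and Bmp4 down. None of 15 contractile genes passed in either count. The elastic fibre list had a median of 0.38 and a mean of -0.005. Several of these changes did not pass within a subtype. Piezo2 changed by 0.40 in subtype 2 (edgeR adjusted p = 0.737) and Dll4 by 1.08 and 0.22 in subtypes 1 and 2 (0.672 and 0.812). In subtype 1 Kcnn4 changed by -0.90 (0.482), Ddah1 by -0.46 (0.865) and Ace by -0.57 (0.961). By contrast, Ptgs1 and Bmp4 (edgeR adjusted p = 0.0354 and 0.04997) were called lower in subtype 2 and Dcn higher in subtype 1.

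In subtype 1 the capillary list (4 members, adjusted p = 0.00542) and the cytokine and chemokine list (5 members, 0.0351) were called up, both with adjusted p = 0.410 with an estimated correlation. Fabp4 was called among the capillary genes over all genes, 2 of them adjusted over the list alone. No member of the cytokine list, which does not hold Ccl5 or Ccl21, was called over all genes by edgeR; the members were Ccl7 (1.21), Il33 (1.17), Tnfsf10 (0.73) and others, all positive. Both lost their call without large 08 (0.166 each), and cytokines also without small 08 (0.266). In subtype 2 the antigen presentation list was called down (6 of 6 members negative, adjusted p = 0.00270), with 0 members by edgeR over all genes and 3 adjusted over the list alone. It had adjusted p = 0.903 with an estimated correlation and kept its call without each sample (highest 0.0484). The capillary list was not called there (5 of 7 positive, 0.345).

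In fibroblasts, Dkk2, Duox1 and Cyp4b1 were among the 7 genes that edgeR called between artery sizes. Dkk2, a secreted Wnt modulator, fell from 46.3 ± 6.40 CPM in large to 10.6 ± 0.27 CPM in small arteries (-2.14 ± 0.17; edgeR adjusted p = 0.00496). Duox1, an oxidase that makes hydrogen peroxide, fell from 35.1 ± 7.87 to 9.21 ± 1.19 CPM (-1.88 ± 0.22; 0.0348), and Cyp4b1, a fatty acid hydroxylase, rose from 7.07 ± 2.80 to 40.4 ± 4.82 CPM (2.38 ± 0.26; 0.0236). Isl1, a developmental homeobox factor, stood at 19.6 ± 5.81 CPM in large and 0.122 ± 0.118 CPM in small arteries (-6.75 ± 0.46; 0.00331). Anxa3, an annexin (-2.45 ± 0.24; 0.0137), and Fgf9, a fibroblast growth factor (-3.18 ± 0.32; 0.0139), were also lower in small arteries. Isl1, Anxa3 and Fgf9 lay under the minimum mean of 20 CPM set for the leading named genes and were among the 5 of lowest p in that direction. These 6 and a gene with only a clone name were all the calls among 10438 genes (1 up, 6 down), with 348 at an unadjusted p under 0.05 and 35 called by DESeq2. With the sample number as a block, 99 genes were called, 7 of them shared.

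Leaving out 1 sample gave 2 calls without large 06, 2 without large 07, 3 without small 06, 1 without small 07 and 1 without small 08, and only Isl1 kept its call in all 6. Dkk2 had adjusted p = 0.059 without small 07 and 0.094 without small 08. Several further genes did not pass without the block and passed with it: Heyl, a Notch target (2.06 ± 0.29; adjusted p = 0.0899, block 2.09e-04), Dpp4, a marker of adventitial progenitors (-2.86 ± 0.38; 0.0689, block 2.58e-04), Kcnj8, a subunit of ATP-sensitive potassium channels (-1.22 ± 0.18; 0.0899, block 0.00167), and Ednra, the endothelin A receptor (1.07 ± 0.19; 0.364, block 0.0104).

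**Figure D3:**
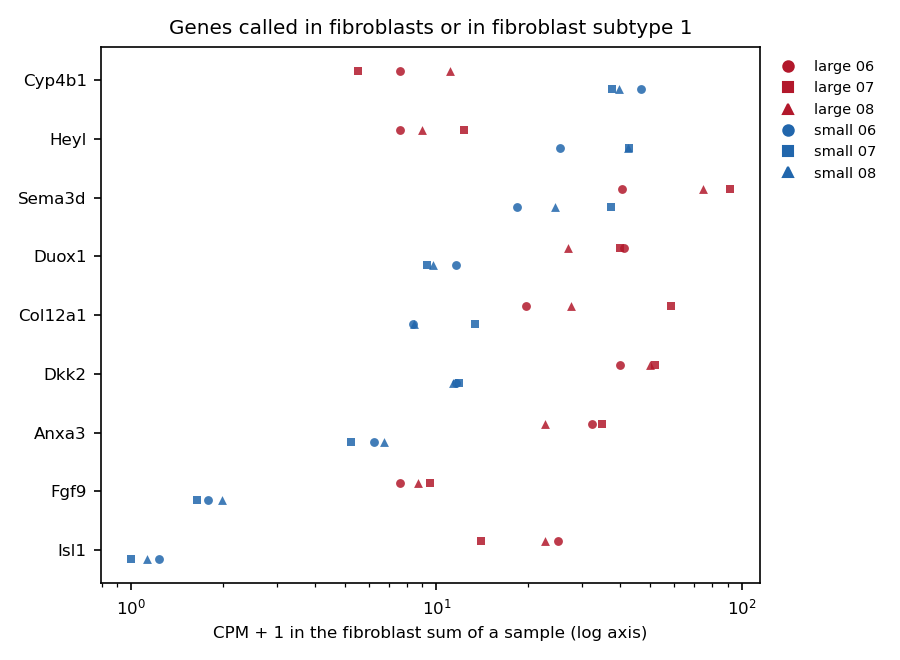
Level of 9 genes in the fibroblast sum of each sample, as CPM + 1 on a log axis, for the 3 large and the 3 small samples. Dkk2 averages 46.3 CPM in large and 10.6 CPM in small samples, and Isl1 19.6 and 0.122 CPM.

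Fibroblasts also fell into subtypes, but these followed the sample number. Subtype 1 made up 2.03% of the fibroblasts of large 06 and 42.5% of small 06, and 97.7% to 99.8% in the other samples (exact permutation p = 0.6 between artery sizes; 0.8 adjusted over 8 subtype shares). In samples 06, subtype 2 held more Apoe, Fmo2, Chchd10 and Ccn2, and less Pi16, Mfap5, Fbn1 and Fn1, genes of the adventitial matrix. Within subtype 1, edgeR called 11 genes. Dkk2 fell from 55.5 ± 7.55 to 10.6 ± 0.52 CPM (-2.29 ± 0.17; adjusted p = 2.90e-04) and kept its call without each sample. Heyl rose from 6.44 to 41.3 CPM (2.23 ± 0.25; 0.00849), and Sema3d, a secreted guidance cue (-1.62 ± 0.23; 0.0304), and Col12a1, a collagen that binds fibrils (-2.27 ± 0.35; 0.0477), were lower in small arteries. Cyp4b1, Duox1 and Anxa3 kept the direction seen over all fibroblasts. DESeq2 called 11 genes as well, and 484 had an unadjusted p under 0.05. The count was 3 without large 06, 7 without large 07, 5 without large 08, 17 without small 06 and 118 without small 07, and the 6 other named genes each lost their call without at least 1 sample. The sum of large 06 rested on 21 cells.

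Of the fixed lists in fibroblasts, 9 were called by camera, none of them with an estimated correlation, where their adjusted p ran from 0.371 to 0.615. With the sample number as a block the hypoxia and glycolysis list was called down as well (adjusted p = 0.0118, and 0.102 without the block). Basement membrane and fibrillar collagen genes leaned toward small arteries, adventitial genes leaned toward large ones, and elastic fibre genes were not called (11 of 17 negative; adjusted p = 0.565). Of 16 basement membrane genes 12 were positive, such as Col4a5 (0.87), Nid2 (0.95) and Col4a1 (0.51), with 0 called by edgeR over all genes (camera adjusted p = 1.72e-04). Of 14 adventitial genes 9 were negative, with Anxa3 called over all genes and 4 down adjusted over the list alone (adjusted p = 5.05e-04). Il33, an alarmin of the adventitia, had a log2 change of -0.72 ± 0.25, from 1317 ± 262 to 800 ± 80.5 CPM. Of 18 homeobox genes 13 were positive, with 0 over all genes and 3 up and 1 down adjusted over the list alone (5.05e-04). Meox2 (1.07 ± 0.29; 119 ± 49.2 to 251 ± 34.6 CPM) and Foxf1 (0.64 ± 0.17) lay higher and Hoxc9 (-1.50) lower. Growth factor (21 of 28 positive) and fibrillar collagen genes (15 of 20 positive; 0.00915 each), contractile (13 of 19 positive) and Notch genes (5 of 6 positive; 0.0242 each) were called up. Mitochondrially encoded genes (11 of 13 negative; 0.0142) and interferon genes (14 of 18 negative; 0.0242), such as Irf7 and Isg15, were called down. Adjusted over the list alone, Heyl was called in the Notch list and 0 members in the basement membrane, growth factor, fibrillar collagen, contractile, mitochondrially encoded and interferon lists.

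The adventitial list stayed called without each sample. Basement membrane genes lost their call without large 06 (0.469) and small 07 (0.446), homeobox genes without large 07 (0.111), small 06 (0.104) and small 08 (0.152), and growth factor genes without small 07 (0.0605). Without large 06 the contractile and fibrillar collagen lists changed direction (0.989 and 0.532). Contractile genes also lost their call without large 07 (0.287) and small 08 (0.515), and fibrillar collagen genes without small 07 (0.280). Notch genes lost it without large 06 (0.0960), large 07 (0.575), small 07 (0.618) and small 08 (0.226), and interferon genes without large 06 (0.419), small 06 (0.0673), small 07 (0.0717) and small 08 (0.0820). Mitochondrially encoded genes lost it without large 07 (0.667), large 08 (0.146), small 06 (0.0755) and small 07 (0.0717).

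Within fibroblast subtype 1, camera called 6 lists up and 3 down, again none with an estimated correlation (0.326 to 0.579). Growth factor (20 of 28 positive; adjusted p = 5.62e-04) and adventitial genes (10 of 14 negative; 5.62e-04) kept their calls without each sample. The fibrillar collagen, basement membrane, homeobox, Notch and proliferation lists were called up, and the mitochondrially encoded and hypoxia lists down. Each of these lost its call without at least 1 sample. The highest adjusted p was 0.689 for fibrillar collagen without large 06 and 0.459 for basement membrane without small 07. It was 0.131 for homeobox and 0.272 for Notch without large 07, and 0.536 for proliferation without large 08. For mitochondrially encoded genes it was 0.156 without large 07, and for hypoxia 0.0889 without small 07. Of the 6 Notch genes, 3 were positive and 3 negative (median log2 change 0.11, mean 0.43), so they had no common direction. Heyl (2.23) was the only one of them called. Over all genes edgeR called Heyl, 1 proliferation gene and Anxa3, and adjusted over the list alone the called lists held 1 Notch, 3 proliferation and 3 homeobox genes up and 5 adventitial, 2 hypoxia, 1 homeobox and 1 growth factor genes down. The contractile list, called over all fibroblasts, was not called here (12 of 19 negative; 0.501).

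Smooth muscle could be compared only between large 08, with 1191 cells, and the 3 small samples, with 1533, 12 and 868 cells. With a lone large sample there is no test of artery size, and genes are given where large 08 lay at least 2-fold beyond all 3 small samples, a rule set after the cell numbers were seen. Large 08 held more of the matrix genes Fbln5, an elastic fibre protein (78.8 CPM, 95% exact Poisson interval 71.4 to 86.7, against 8.59 ± 2.43; 9.17-fold), Ccn2, connective tissue growth factor (4504 CPM, 4448 to 4562, against 790 ± 507; 5.70-fold), and Ccn3 (1357 CPM, 1326 to 1389, against 247 ± 106; 5.50-fold). Rcan1, an inhibitor of calcineurin, was 5.30-fold and Clu, clusterin, 4.04-fold higher in large 08. Small samples held more Fabp4 (500 ± 191 against 19.3 CPM, 15.7 to 23.4; 26.0-fold) and Sncg, a synuclein (2042 ± 68.0 against 82.3 CPM, 74.8 to 90.4; 24.8-fold). Igfbp5 stood at 621, 2076 and 969 CPM in small 06, 07 and 08 against 80.8 CPM, and Angptl4 at 53.1, 159 and 59.9 against 4.30 CPM, both highest in small 07 with its 12 cells. Small samples also held more Col4a4, a basement membrane collagen (124 ± 30.3 against 10.5 CPM), and Calcrl, the receptor of calcitonin gene-related peptide (86.6 ± 33.7 against 8.05 CPM, 5.82 to 10.8; 10.8-fold). The intervals cover counting error only.

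By this rule large 08 stood apart in 151 of 4037 genes, 51 higher and 100 lower. The same rule set small 06 apart in 4 genes, small 07, with its 12 cells, in 755 and small 08 in 0. Without small 06, small 07 or small 08 the count for large 08 was 185, 188 or 212. Of 20 contractile genes none passed the rule, but their median log2 difference of -0.54 put them below all of 10000 random lists matched on expression, toward large 08 (Acta2 42042 against 20892 ± 10629 CPM, Cnn1 3057 against 1219 CPM). Basement membrane (median -0.99), fibrillar collagen (-0.65) and elastic fibre genes (-0.31) also leaned toward large 08, with Col6a1 3.05-fold and Lox 2.44-fold higher there. Other collagen and proteoglycan genes ran the other way, with Fmod at 29.8 CPM in large 08 and 70.7, 193 and 85.4 CPM in the small samples, and Dcn at 117 CPM and 215, 1032 and 291 CPM. Fatty acid genes (0.90; 5 of 10 lower in large 08), capillary genes (1.30), homeobox genes (0.89) and vasoactive receptors (0.54; 2 of 8) leaned toward small arteries. So did immediate early and dissociation stress genes (0.54, above all random lists; 3 of 21), such as Junb at 602 CPM in large 08 and 1554 to 2342 CPM in the small samples, growth factor genes (0.34; 4 of 18 lower and 2 higher in large 08, Ccn2 among the latter), and adventitial fibroblast genes (1.06; 2 of 4). Fibroblast markers in the smooth muscle sums were 1845 CPM in large 08 and 1344, 8001 and 1722 CPM in the small samples. Among the receptors Ednra stood at 73.7 ± 5.60 CPM in small samples and 29.9 CPM in large 08, and Npy1r, the neuropeptide Y receptor of vasoconstriction, at 189 ± 74.2 and 74.1 CPM. The 7 ion channels leaned toward large 08 (median -0.31, percentile 1.98 of the random lists), and 1 passed the rule, in the other direction. This was Kcnab1, a potassium channel subunit, at 43.5 ± 2.34 CPM in small samples and 14.2 CPM in large 08. These values describe 4 libraries and carry no test of artery size.

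**Figure D4:**
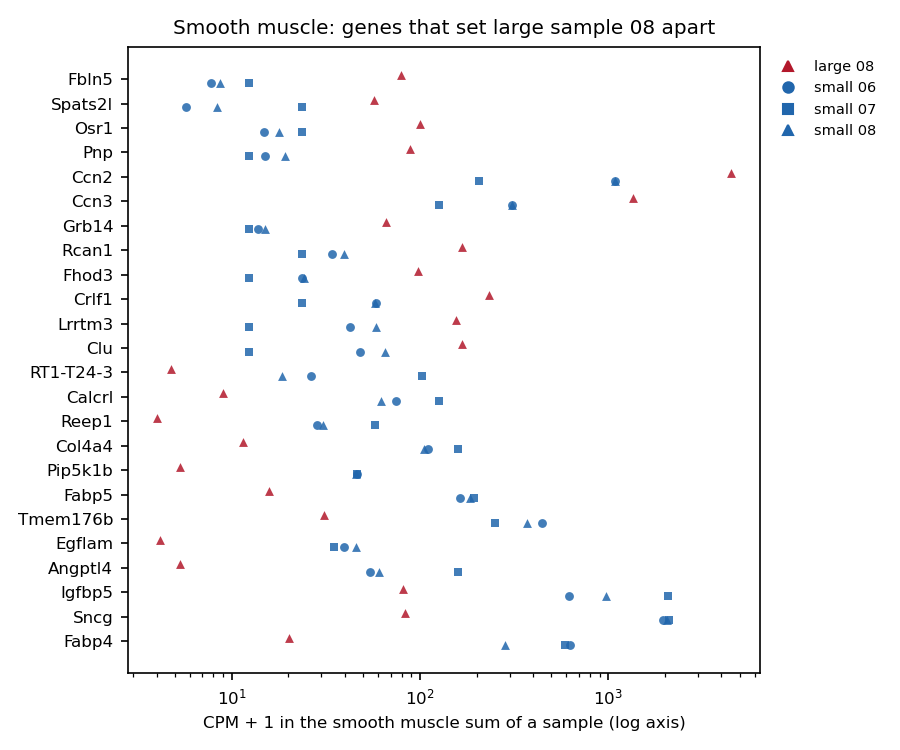
Level of 24 genes in the smooth muscle sums, as CPM + 1 on a log axis, in large 08 and the 3 small samples. Fabp4 and Sncg lie at 19.3 and 82.3 CPM in large 08 and average 500 and 2042 CPM in the small samples.

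Immune cells gave no gene past the threshold, and the genes named are among those of lowest p in their direction. Tgfbi, an adhesion protein of macrophages, stood at 71.3 ± 39.5 CPM in large and 284 ± 36.7 CPM in small arteries (1.99 ± 0.37), and Cd8a, of cytotoxic T cells, at 279 ± 39.9 and 128 ± 27.6 CPM (-1.14 ± 0.24). Cd79a, of the B cell receptor (-1.89 ± 0.29), Tnfrsf17, of plasma cells (-2.08), and E2f2 (-1.65) were lower in small arteries, and Pink1 (1.39 ± 0.23) and Wwp1 (1.83) higher; all had edgeR adjusted p = 0.349. Macrophage markers summed to 8149 ± 4972 CPM in large and 18313 ± 3001 CPM in small arteries (n = 3; exact permutation p = 0.1), and T cell markers to 1749 ± 844 and 1164 ± 125 CPM (p = 0.3). edgeR called 0 of 8211 genes, with 906 at an unadjusted p under 0.05, and DESeq2 called 13. Without large 08 edgeR called 159 genes. No immune subtype share passed.

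Of the lists in immune cells, 10 were called up and 2 down by camera, each with adjusted p of at least 0.513 with an estimated correlation. Growth factor genes had 14 of 16 members positive (adjusted p = 5.43e-06), and fibrillar collagen (1.82e-04), elastic fibre (0.00263), basement membrane, cytokine and fatty acid genes (0.00712 each) were also up. Contractile genes (0.0156), vasoactive receptors (0.0173), the nitric oxide list (0.0202) and adventitial genes (0.0251) completed the upward lists. All 14 proliferation genes (0.0275) and all 13 mitochondrially encoded genes (0.0173) were negative. Adjusted over the list alone, 3 growth factor genes and 1 gene each of the receptor, elastic fibre and fatty acid lists were up, with 0 by edgeR over all genes. Without large 06 the growth factor, fatty acid, mitochondrially encoded and proliferation lists kept their calls, 7 others lost theirs (0.0831 to 0.995) and basement membrane was not tested. Proliferation genes lost theirs without large 07 (0.229), large 08 (0.140), small 06 (0.0733) and small 08 (0.103), mitochondrially encoded genes without large 07 (0.227) and small 06 (0.101), and the nitric oxide list without small 06 (0.0935) and small 07 (0.105). Fibroblast markers in immune sums were 156, 556 and 1030 CPM in the large samples and 960, 1361 and 1715 CPM in the small samples (exact permutation p = 0.2).

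The class labelled neuron held Schwann cell genes more than neuronal ones, and no gene passed. Cdh19, a cadherin of Schwann cells, was at 169 CPM in large and 660 CPM in small arteries (1.86 ± 0.41; edgeR adjusted p = 0.893) and Il33 changed by -1.16 ± 0.32 (0.893). Schwann markers summed to 618 ± 482 and 2419 ± 499 CPM (n = 3; exact permutation p = 0.1), neuron markers to 56.5 ± 25.9 and 33.3 ± 14.5 CPM, and fibroblast markers to 11272 ± 8479 and 17623 ± 6564 CPM (p = 0.4). edgeR called 0 of 1122 genes, with 46 at an unadjusted p under 0.05, and DESeq2 called 0. Fibrillar collagen genes (13 of 14 positive; camera adjusted p = 0.00121) and basement membrane genes (5 of 5 positive; 0.0126) were called up, with 0 and 2 members adjusted over the list alone and 0 by edgeR over all genes. Both had adjusted p = 0.479 with an estimated correlation. Both lost their call without large 06 (0.0889 each), and basement membrane genes also without large 08 (0.107) and small 08 (0.0697). The class was a mixture: the authors' further label put 337 of its 865 cells with fibroblasts and 78 with smooth muscle.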

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

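The tests of the barcode filter, of lysis, of artery size, of an effect on every cell, of the endothelial subtype mix and of free RNA behind genes higher in large arteries were chosen only after the result was seen, as was the comparison of the effect between endothelial cells and fibroblasts.

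The difference between artery sizes differed between endothelial cells and fibroblasts in 394 genes by an edgeR interaction test, with 217 more positive and 177 more negative in endothelium. Lsamp fell by 5.83 on the log2 scale in endothelial cells and changed by -0.03 in fibroblasts (interaction -6.01 ± 0.59; adjusted p = 1.02e-04), and Frzb had an interaction of -4.54 ± 0.65 (0.00141). Cxcl12, a chemokine, stood at 0, 0 and 0.563 CPM in the large and 22.2, 3.62 and 90.9 CPM in the small endothelial sums (interaction adjusted p = 0.00422). The small fibroblast sums held 52.8, 139 and 78.9 CPM of it, so in small 08 its level was higher in endothelium than in fibroblasts. Of the 10 genes of largest interaction, Tnfaip6, Olfml1, Clmp, Enpp3, Abca8a and Slit2 are rich in fibroblasts and lay at or near 0 in large endothelial sums. Only 2 of the 10 kept their call without each sample, and the count fell to 172 without large 08. The same test between smooth muscle and endothelial cells gave 1090 genes, but it rests on a lone large smooth muscle sample, assumed to vary like the others, and fell to 132 without small 06 and to 125 without small 08. A signal in data that the comparisons do not use came from the left-out barcodes, of which 2148 carried at least 20 smooth muscle marker UMIs per 10000 (3, 1 and 458 in the large and 1042, 23 and 621 in the small samples).

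The endothelial difference is the first pattern weighed. Of the 645 genes, 403 could be tested within subtype 1, where the fold changes shrank to a median of 0.420, and 302 within subtype 2, where they shrank to 0.192. The shares of the subtypes alone gave a median of 0.640 of the change. The shift from arterial to lymphatic endothelium may therefore account for much of the pattern, including Nos3, Gja5, Prox1 and Kdr, but the ratio in subtype 1 lies between the bounds set for the test and the sums within subtypes are thinner, so mix and change within cells cannot be told apart for the genes as a set. Free fibroblast RNA is argued against as the main cause in either direction: fibroblast markers were at least 1.66 times as high in each small as in each large sample, against what genes higher in large arteries need, and 8.87% of the genes higher in small arteries were at least 10 times as abundant in fibroblasts. Within subtype 1 the same RNA could give at least 0.5 of the rise for 30.8% of the 13 genes higher in small arteries, among them Dcn (0.730), C1s (0.640), F3 (0.592) and Igfbp6 (0.509), while Igf2 and Rgs10 (0.00467) had almost none of theirs from it. Dcn is itself one of the fibroblast markers behind this estimate, so its ratio is partly set in advance. Ccl21 (0.0305), Ccl5 (0.00182) and Hbb-bs (6.17e-04) had little from fibroblast RNA too, but they are transcripts of lymphatic, T and red blood cells, and RNA from such cells stays open for them. Fabp4 (0.00187) had little from it as well, and rose from 21.4 to 346 CPM in subtype 1 and from 8.97 to 151 CPM in subtype 2. In smooth muscle it stood at 19.3 CPM in large 08 and 500 CPM on average in small samples. RNA from a source shared by these cells was not tested for Fabp4 and stays open. How much perivascular tissue with lymphatic vessels was dissected along with each artery size was not tested.

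The second pattern is the near absence of smooth muscle cells from large 06, large 07 and small 07. The filter on barcodes is argued against, since at most 23 left-out barcodes carried a smooth muscle signal in these samples. Artery size alone is argued against, because the share varied by at least 7.24 percentage points within each size and by 1.00 between their means. This spread is part of the pattern itself and no separate test, and a part played by artery size stays open, as untested. Lysis after the wash would leave smooth muscle UMIs in the other cells: large 06 and large 07 held at most 0.238 per cell, below the 0.342 of the lowest sample rich in smooth muscle, and at most 78.2 CPM when scaled to the UMIs of those cells, below its 192 CPM, which argues against it there. Small 07 lay above that sample per cell (0.489) but below it when scaled (135 CPM), so lysis there cannot be told from its absence. Lysis before the wash and incomplete digestion of the media in these samples stay open as untested explanations.

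The third pattern is fibroblast subtype 2, at 98.0% and 57.5% of fibroblasts in large 06 and small 06 and at most 2.32% elsewhere. Artery size alone is argued against, as the share varied by at least 57.3 percentage points within each size and by 14.1 between their means, which is again part of the pattern itself. Low depth is argued against, since its cells had at least 0.620 of the median UMIs of subtype 1. At most 7.64% of fibroblasts in samples 07 and 08 lay nearer to subtype 2 over 24 genes, so few cells there resembled it. These genes were picked for their difference between the labels in samples 06. Of the cells labelled subtype 2 in samples 07 and 08, only 36.2% to 55.6% lay nearer to it. The measure thus comes from the labels and follows them poorly there, so it cannot decide whether the label alone made the pattern. In small 06 the subtype's genes also parted the other cells from those of small 07 and 08 (correlation across genes at least 0.224 in endothelial and immune cells), so an effect on every cell of that sample, or free fibroblast RNA in it, may contribute. With the same profile, large 06 gave 0.232 in endothelial and 0.194 in immune cells, on both sides of the bound of 0.2, so such an effect there cannot be told from its absence. The profile of large 06 itself rests on 21 cells of subtype 1 and decides nothing. What samples 06 share, such as animals or day, is not given in the labels and stays open, as untested.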

How the results depend on the processing

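The subtype tests, the interaction of endothelial cells with fibroblasts, the smooth muscle rule, the removal of high doublet scores, the further cell type label and the fits on samples 07 and 08 or 06 and 08 alone were alternatives chosen only after the result was seen; the others were planned. Of 112 endothelial genes named, 55 kept direction and call in every setting, 44 lost a call in at least 1, 13 gained one and 0 reversed. For fibroblasts the numbers were 71, 6, 15 and 0 of 101, and 9 genes that were not called changed sign in some setting. In immune cells 71 of 97 genes kept both, 18 gained a call and 8 uncalled genes changed sign, and in the neuron class 42 of 63 kept both and 21 uncalled genes changed sign. Endothelial genes called numbered 645, and 1147 with no filter, 1144 with the sample number as a block, 297 with samples 07 and 08 alone and 222 to 628 with 1 sample left out. In endothelial subtype 1 the 25 calls became 11 by DESeq2, 176 with the block and 3 to 145 with 1 sample left out; in subtype 2 the 9 became 14, 41 and 0 to 26. In fibroblasts the 7 calls became 35 by DESeq2, 99 with the block, 2 with samples 07 and 08 alone, 1 with samples 06 and 08 alone and 1 to 6 with 1 sample left out; in fibroblast subtype 1 the 11 became 147 with the block and 3 to 118. The 0 calls by edgeR in immune cells, with 906 at an unadjusted p under 0.05, became 13 by DESeq2, 15 with no filter and 0 to 159 with 1 sample left out, and the 0 in the neuron class, with 46 at an unadjusted p under 0.05 and 0 by DESeq2, became 11 with no filter. The fits on fewer samples or fewer genes differ by construction; for the other changes the cause was not tested.

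With an estimated correlation 0 lists were called in any cell type, and fry called 6 in endothelium, 1 in fibroblast subtype 1 and 0 in fibroblasts, immune cells, the neuron class and both endothelial subtypes. Leaving out 1 sample gave 1 to 3 lists in endothelium, 5 to 10 in fibroblasts, 6 to 12 in immune cells, 1 to 3 in the neuron class, 1 to 7 in endothelial subtype 1, where the block gave 5, 1 to 3 in endothelial subtype 2 and 7 to 10 in fibroblast subtype 1. In fibroblasts the contractile list ran from 2.35e-06 without large 08 to 0.989 without large 06, and the fibrillar collagen list from 9.82e-06 to 0.532, both reversed without large 06; the cause was not tested. The interaction of smooth muscle with endothelium gave 369 genes by DESeq2 and 125 to 1430 with 1 sample left out. That of endothelium with fibroblasts gave 218 by DESeq2, 119 with endothelial subtype 1 only and 172 to 495 with 1 sample left out. The 151 smooth muscle genes became 1250 by edgeR and 48 by DESeq2 with 1 large sample against 3, and 1361 by edgeR with no filter; these fits assume that the lone sample varies like the small ones. The share difference of smooth muscle, in percentage points, ran from -4.11 without large 07 to 5.19 without large 08, and that of fibroblast subtype 1 (14.1) from -17.9 without large 06 to 33.0 without small 06. Paired by number, the share differences were the same, and the smallest p of a sign-flip test with 3 pairs is 0.25. For genes of smooth muscle, no paired analysis was possible because only number 08 had at least 10 smooth muscle cells in both sizes. In immune cells and in the subtypes, sums of the same libraries, at least 1 pair correlation lay under 0.1, so whether equal numbers pair the samples stays unsettled. The correlations were -0.0105, 0.0230 and 0.269 in immune cells, where the block gave 0 calls. Every sample correlated best with its own number in endothelial subtype 1, but not in endothelial subtype 2, fibroblast subtype 1 or immune cells. The subtype sums are shallow, with 17 cells of endothelial subtype 1 in small 07 and 14 to 47 cells of fibroblast subtype 2 outside samples 06.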

Other observations

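The levels, the tests of other splits of endothelial cells, fibroblasts, immune cells, the neuron class and the interaction, and those of lists in endothelial subtype 2 and fibroblast subtype 1 were chosen only after the result was seen, while the other splits of the subtypes were written down before.

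Across both artery sizes the cell types parted by receptors and channels of vascular tone. Smooth muscle held P2rx1, an ATP-gated channel, at 196 ± 44.3 CPM (SD, n = 4; 172-fold the next type), Npy1r at 156 ± 76.8 CPM (51.4-fold) and Kcnma1, the large-conductance potassium channel, at 27.4 ± 6.87 CPM (24.4-fold). Fibroblasts (n = 6) held Agtr1a, the main angiotensin II receptor, at 123 ± 21.4 CPM (3.23-fold the next type), Bdkrb2, a bradykinin receptor, at 114 ± 35.4 CPM (13.6-fold), Ptgir, the prostacyclin receptor, at 113 ± 29.4 CPM (5.01-fold) and Ptgs2, the inducible cyclooxygenase, at 194 ± 116 CPM (12.5-fold). The next type was sought among all classes, including the mixed neuron class, part of which the further label places with fibroblasts. Endothelium held Ramp2, a partner of Calcrl, at 1773 ± 305 CPM, Calcrl itself at 442 ± 141 CPM and Ece1, which activates endothelin, at 748 ± 171 CPM. Gja4 was shared by smooth muscle (227 ± 14.7 CPM) and endothelium (209 ± 75.3 CPM). Immune cells led in Tbxas1, the thromboxane synthase (34.9 ± 18.6 CPM; 17.3-fold). Within endothelium, Igf2 was at 457 CPM in subtype 1 and 14.8 CPM in subtype 2, and Ace at 42.8 CPM and 0.

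With 3 samples against 3 there are 10 splits, too few for a share under 0.05. For endothelial genes the real count was 645 and the highest other 4, with 1 split as high. For fibroblast genes they were 7 and 1 (1 split), for endothelial subtype 2 genes 9 and 8 (1 split), and for the interaction of endothelium with fibroblasts 394 and 3 (1 split). Of the splits that part all 3 number pairs, the other endothelial splits called at most 4 genes and the other fibroblast splits 0. For edgeR in immune cells (906 at an unadjusted p under 0.05, DESeq2 13) and the neuron class (46, DESeq2 0) the real counts were 0 and the highest others 0 and 1 (10 splits each). In endothelial subtype 1 the real count was 25 and the highest other 42, from large 06, small 06 and small 08 against the rest (2 splits as high). In fibroblast subtype 1 it was 11 against 567, from large 06, large 07 and small 07 against the rest (2 splits as high), which points to a structure of the samples: these 3 samples have the fewest kept cells, at most 12 smooth muscle cells each, and the highest median UMIs per cell in the subtype (at least 2069, against at most 1896 in the others), and which of these matters was not tested. For lists the real and highest other counts were 3 and 6 in endothelium (5 splits), 9 and 12 in fibroblasts (3 splits), 12 and 16 in immune cells (3 splits), 2 and 2 in the neuron class (5 splits), 2 and 7 in endothelial subtype 1 (9 splits), 1 and 5 in endothelial subtype 2 (8 splits) and 9 and 7 in fibroblast subtype 1 (1 split).

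Doublet scores placed left-out barcodes inside the range of the kept cells above the kept cells in 72.1% (small 07) to 86.7% (large 06) of pairs. Erythroid transcripts were uneven between samples, with hemoglobin and related markers at 2728 ± 4692 CPM in large and 2724 ± 2814 CPM in small endothelial sums and 8145 CPM in large 07.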
